A study of Mus musculus with 6 samples.

How the data were processed

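Nuclei from the pons and medulla of male C57BL6/J mice were profiled by droplet sequencing (10x Genomics 3' chemistry), in 3 libraries from mice exposed to chronic intermittent hypoxia (CIH) and 3 from mice in room air. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) for 32285 genes, made by the authors with Cell Ranger before deposit. The version is 6.1.2 per the file headers and 3.1.0 in the submitters' processing notes, which also name Seurat 4.0 and the mm10 genome. Whether intronic reads were counted is not stated. The labels do not say how many mice made up a library. Gene positions came from GENCODE mouse release M21 on mm10, in which 32235 of the genes were matched.

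Of 43836 barcodes, 40139 had at least 500 genes detected and at most 5% mitochondrial UMIs. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold, which was the planned rule, marked 1, 1 and 703 nuclei in the CIH libraries and 0, 2 and 1308 in the normoxia libraries. The top-scoring nuclei, 0.8% per 1000 barcodes of a library, were therefore removed instead (160, 170, 1024, 190, 392 and 749 in the same order), a change made after the data were seen, and the automatic threshold was kept as an alternative. This left 37454 nuclei. Counts were log-normalized, 3000 variable genes, 30 principal components and 15 neighbours were used, and clusters were found with leidenalg 0.10.2 at resolution 1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9). Neurons were clustered again alone, which gave 56 clusters in all. Clusters were named from marker genes fixed beforehand, while the score thresholds (2 for a class, 2.5 for granule neurons, 3-fold for a transmitter) were set after the clusters were seen. The 14 named classes held 27949 nuclei, and 9505 nuclei stayed unnamed, in clusters with mixed markers, with more markers of another class, with mitochondrial RNAs in the lead, of other cerebellar-marker neurons or of neurons absent from a library.

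UMIs were summed per library over all kept nuclei and over each class in which every library had at least 20 nuclei. Sums were compared between groups with edgeR 4.0.16 (R 4.3.3; trimmed mean of M-values scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment within a class, threshold 0.05). DESeq2 1.42.0 was run on the same sums. Differences in effect between classes were tested with limma 3.58.1 on the difference in log2 CPM (counts scaled to each library's sum) between 2 classes of a library (prior count 1). Shares were compared by an exact permutation test over 20 assignments of libraries. Lists of genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, where at least 5 members were measured. Standard errors are those of the log2 fold change. The comparisons, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined.

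Genes were named by this rule: up to 10 higher and 10 lower genes per class by smallest p, among those with adjusted p under 0.05 and no overlap between the groups; for each list up to 4 members of smallest p in the class where the list had its smallest p; Vegfa, Slc2a1, Pdk1 and Ldha in all nuclei; and in a class with no call, genes among the 5 of smallest p as values, predicted genes being left out there in astrocytes, excitatory neurons and fibroblasts. Called genes with the symbol of a predicted gene were to be counted and not named, and there were 0 among the calls within classes. A gene outside the rule is said to have been chosen after its values were seen.

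Alternatives were RLE size factors, DESeq2, no filter on low counts, the replicate number as a block, the median UMIs per nucleus as a covariate, leaving out each library, nuclei with at least 1000 genes and at most 1% mitochondrial UMIs, doublets kept, resolution 2, a centred log-ratio for shares and adjustment over all classes together. Added after the data were seen were the automatic doublet threshold and sums or shares over named nuclei other than granule neurons. The procedures were tested on simulated data: counts drawn from the libraries' own spread, with genes changed 2-fold or 4-fold. Recovery in all nuclei was 59% of 2-fold and 91% of 4-fold changes, with 8 false calls among 158. A shifted list was recovered by camera with the preset correlation in 11 of 11 sums (all nuclei, all neurons and 9 classes), with 1 false list call in astrocytes. Camera with an estimated correlation and fry each recovered it in 10 of 11, missing it in endothelial cells, and fry made 1 false call in all neurons. Simulated genes were drawn independently of each other. In the data the estimated correlation between list members was, for example, 0.541 for glucocorticoid-responsive genes in oligodendrocytes. Recovery and false calls of lists under such correlation were therefore not tested.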

Results

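Single-nucleus RNA sequencing was performed on the pons and medulla of male C57BL6/J mice, the brainstem region that holds the circuits for breathing and autonomic control. Mice in the exposed group spent 21 days in chronic intermittent hypoxia (CIH), from postnatal day 22 to 43. Nitrogen was let in for 60 seconds until the chamber held 4.5 to 5% oxygen, and air then restored 21% oxygen within up to 5 minutes. The cycle was run 80 times a day over 8 hours. The control group stayed in room air (normoxia). The question the design addresses is which cell classes and genes of the brainstem differ after CIH. There were 3 libraries per group. The labels do not say whether a library came from 1 mouse or from a pool, so p-values measure the spread between these libraries.

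The libraries held 4607, 4770 and 12032 barcodes with 26733243, 28534969 and 40750363 unique molecular identifiers (UMIs) in CIH. The normoxia libraries held 5049, 7405 and 9973 barcodes with 30260893, 37399822 and 46754345 UMIs. After filtering and doublet removal 37454 nuclei were kept, with a median of 2941.5, 3360 and 2262 UMIs per nucleus in the CIH libraries and 3549.5, 2833 and 2895 in the normoxia libraries. The third CIH library stood apart. Its median mitochondrial share was 0.369%, against 0.065 to 0.097% in the other 5 libraries, and 27.15% of its nuclei lay in unnamed clusters led by mitochondrial RNAs, against 3.27 to 11.46% elsewhere. In sums over all nuclei the first and second libraries of each group were close to each other, with a chi-square per gene of 2.52 in CIH and 3.17 in normoxia. All other pairs lay between 16.6 and 62.1, the third normoxia library against the other normoxia libraries (26.8 and 21.2) included. The 3 libraries of a group were thus not equally far apart, and the labels do not say why. Genome positions below are those of GENCODE release M21 on mm10.

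Oligodendrocytes were the most abundant named class in both groups, at 24.6 ± 1.87% of kept nuclei in CIH and 30.7 ± 2.78% in normoxia (mean ± SD over 3 libraries). Excitatory neurons made up 7.06 ± 0.29% in CIH and 12.7 ± 2.39% in normoxia. Inhibitory neurons made up 7.25 ± 2.29% and 14.3 ± 2.84%, and microglia, the resident immune cells of the brain, 3.35 ± 0.75% and 4.58 ± 0.36%. Values were higher in CIH for endothelial cells of the blood vessels (3.02 ± 1.88% against 1.02 ± 0.29%), fibroblasts (1.76 ± 0.41% against 0.92 ± 0.35%) and mural cells (0.84 ± 0.82% against 0.25 ± 0.07%). Noradrenergic neurons made up 0.04 ± 0.03% and 0.13 ± 0.04%, and neurons without a transmitter call 0.35 ± 0.18% and 1.07 ± 0.25%. In each of these 9 of 14 classes every CIH library lay on one side of every normoxia library, which chance gives for 10% of classes. Shares within a library depend on each other, so the 9 classes are not independent and cannot be tested against that 10%. Some counts were small. Noradrenergic neurons numbered 3, 1 and 2 nuclei in the CIH libraries and 7, 5 and 13 in the normoxia libraries. Mural cells numbered 14, 17 and 172 and 12, 11 and 27 in the same order. Cerebellar granule neurons, which lie outside the pons and medulla, made up 24.8, 27.4 and 6.73% of the 3 CIH libraries and 8.58, 8.02 and 5.85% of the normoxia libraries. Astrocytes made up 8.71% of the third CIH library and 1.46 to 1.92% of the other 5. Oligodendrocyte precursors (1.88 ± 1.36% in CIH, 1.16 ± 0.19% in normoxia), perivascular macrophages (0.39 ± 0.05% and 0.43 ± 0.05%) and serotonergic neurons (0.27 ± 0.08% and 0.36 ± 0.02%) overlapped between the groups. Without the third CIH library the difference in percentage points went from 2.0 to 0.92 for endothelial cells, 0.59 to 0.11 for mural cells, -1.24 to -0.80 for microglia, 2.43 to 0.10 for astrocytes and 0.72 to -0.06 for oligodendrocyte precursors, and from 12.15 to 18.6 for granule neurons.

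The exact permutation test chosen for shares could not pass: with 3 libraries against 3 its smallest two-sided p is 0.1, which becomes 0.16 after Benjamini-Hochberg adjustment over 14 classes. Nuclei were sorted before loading, and both the sort and the dissection can set shares. As a percentage of named nuclei other than granule neurons, a denominator chosen after the data were seen, the oligodendrocyte difference turned from -6.16 to 0.58 percentage points. Excitatory neurons stayed lower in CIH by -5.30 and inhibitory neurons by -7.15. The microglia difference went from -1.24 to -0.45, and those of endothelial cells, fibroblasts, mural cells and astrocytes from 2.0 to 3.93, 0.85 to 1.89, 0.59 to 1.11 and 2.43 to 4.73. Unnamed nuclei made up 25.5 ± 7.58% of kept nuclei in CIH and 23.3 ± 5.82% in normoxia.

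**Figure D1:**
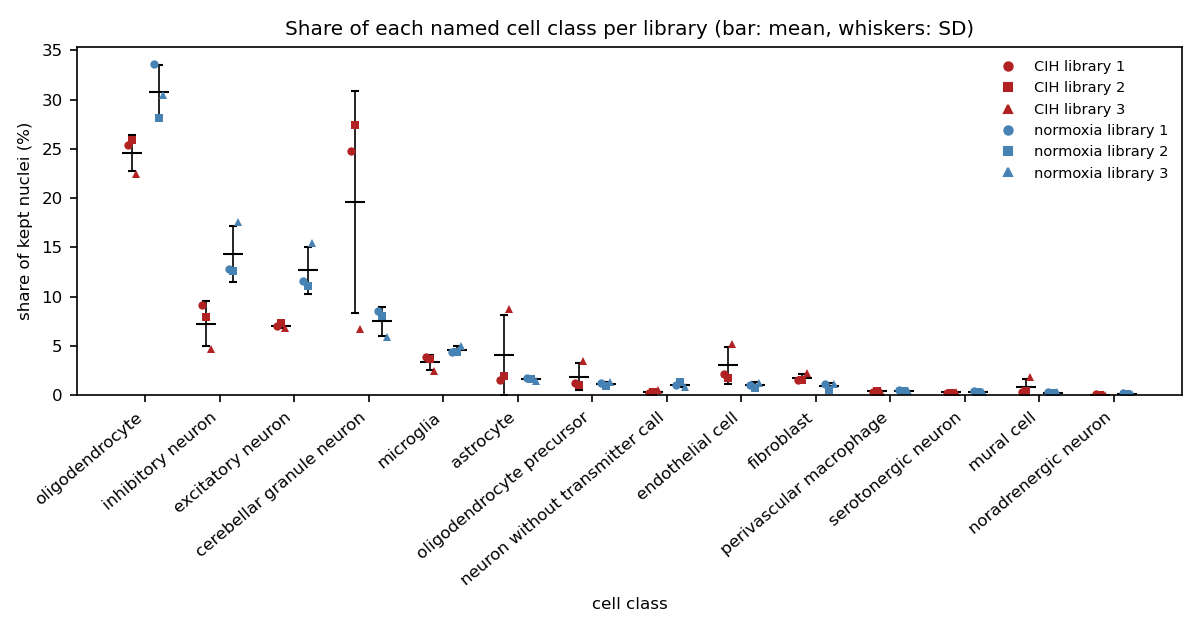
Share of each named cell class among kept nuclei (y axis, percent) in each of the 6 libraries (points), with the group mean (bar) and SD (whiskers). Excitatory neurons sit between 6.77 and 7.34% in CIH and between 11.06 and 15.42% in normoxia, and granule neurons reach 24.75 and 27.43% in the first and second CIH libraries only.

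In all nuclei summed per library, the genes nearest the threshold were all higher in CIH and did not pass it. They were Tcf7l2, a transcription factor of the Wnt pathway (log2 fold change 1.15, SE 0.094, adjusted p = 0.0571 in edgeR), and Ocln, which encodes the tight-junction protein occludin (1.50, SE 0.128, adjusted p = 0.0571). Next came Lef1, another Wnt pathway transcription factor (2.01, SE 0.189, adjusted p = 0.0639), Ror1, a Wnt receptor (0.88, SE 0.084, adjusted p = 0.0639), and the transcription factor Nfib (0.53, SE 0.056, adjusted p = 0.0978). These sums mix cell classes whose shares differed: Lef1 is among the defining genes of endothelial cells and Ror1 among those of unnamed clusters with cerebellar markers. Within endothelial cells Lef1 had a log2 fold change of -0.05 (SE 0.217), and within granule neurons Ror1 had 0.12 (SE 0.206). Each of the 5 genes was higher in 3 of 3 CIH libraries than in every normoxia library. The textbook targets of hypoxia-inducible factors did not pass either: Vegfa had a log2 fold change of 0.20 (SE 0.119, adjusted p = 0.56) and the glucose transporter gene Slc2a1 0.90 (SE 0.354, adjusted p = 0.456). Pdk1 had -0.25 (SE 0.116, adjusted p = 0.51) and the lactate dehydrogenase gene Ldha 0.54 (SE 0.167, adjusted p = 0.413). Slc2a1 read 0.32 and Pdk1 -0.14 without the third CIH library, and Vegfa read 0.13 without the second and 0.32 without the third normoxia library.

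edgeR called 0 of 19548 genes in all nuclei, with 2053 genes at an unadjusted p under 0.05 (977 expected by chance), and DESeq2 called 178. Leaving out the third CIH library gave 487 calls in edgeR, of which 368 were higher in CIH. Of those 368, 84.8% were over 2-fold more abundant in granule neurons than in the other named nuclei, against 5.1% of all genes tested.

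In oligodendrocytes, the myelin-forming cells, Hif3a rose and Fam13c fell in CIH. Hif3a, which encodes an alpha subunit of the hypoxia-inducible factors, went from 3.13 ± 0.289 to 17.1 ± 3.86 CPM (UMI counts scaled to the library's effective size; mean ± SD over 3 libraries), a log2 fold change of 2.47 (SE 0.236, adjusted p = 0.0191 in edgeR). Fam13c went from 510 ± 11.4 to 334 ± 15.2 CPM, a log2 fold change of -0.61 (SE 0.07, adjusted p = 0.0466). Hif3a (ENSMUSG00000004328) lies on chromosome 7 from 17031507 to 17062427 on the minus strand and Fam13c (ENSMUSG00000043259) on chromosome 10 from 70440481 to 70558736 on the plus strand. Both differences were present in all 3 CIH libraries against all 3 normoxia libraries, as the rule for naming genes requires. They were also present within each of the 4 oligodendrocyte clusters, which come from the same libraries and are not independent of each other. In cluster 6 Hif3a lay near the floor, at 2.6 CPM in CIH and 0.3 CPM in normoxia.

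These were 2 of 12990 genes tested in oligodendrocytes, and 807 had an unadjusted p under 0.05 (650 expected by chance). DESeq2 called 30 and a fit with the replicate number as a block called 120. Leaving out 1 library gave 12 calls without the third CIH library, 6 without the third normoxia library, 1 without the second CIH library and 0 without any of the other 3. The Hif3a call ended without the first CIH library (adjusted p = 0.0665), the first normoxia library (0.185) or the second normoxia library (0.272), with log2 fold changes from 2.24 to 2.56 over all libraries left out. The Fam13c call ended without any of those 3 or the second CIH library (adjusted p from 0.163 to 0.452). Adjusted over all classes together, the values were 0.0663 and 0.129. Over 17 settings Hif3a passed in 13 (adjusted p from 1.3e-11 to 0.272) and Fam13c in 8 (1.53e-06 to 0.452).

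Glucocorticoid-responsive genes stood higher in CIH oligodendrocytes, with 17 of 17 measured members above their normoxia level and a median log2 fold change of 0.81. None passed over all genes, and 11 passed when adjusted over the list alone. They included Plin4, a lipid droplet coat protein gene (2.35, SE 0.449), Fkbp5, an immunophilin gene induced through the glucocorticoid receptor (2.24, SE 0.441), the kinase gene Sgk1 (1.19, SE 0.261) and Arrdc2 (0.85, SE 0.215), with adjusted p over the list alone of 0.00449, 0.00449, 0.00636 and 0.0126. The list was called by camera with its preset correlation (adjusted p = 1.16e-12) and not with an estimated one (adjusted p = 0.68 with an estimated correlation). Without the third CIH library the median was 0.29, Fkbp5 read 1.44 and Arrdc2 0.50, and 4 members passed when adjusted over the list alone. Astrocyte markers also stood higher in CIH oligodendrocytes, with a median log2 fold change of 0.58 over 8 markers, and -0.13 without the third CIH library. The 3 endothelial markers measured there had a median of 0.77, and 0.48 without it. In the same nuclei 3 further lists were higher with the third CIH library and not without it: mitochondrially encoded RNAs for 13 of 13 members (median 0.35, and -0.02 without it), ribosomal protein genes for 61 of 63 (0.21, and -0.16) and oxidative phosphorylation genes for 49 of 50 (0.24, and -0.23). Their adjusted p was 0.68, 0.768 and 0.802 with an estimated correlation.

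**Figure D2:**
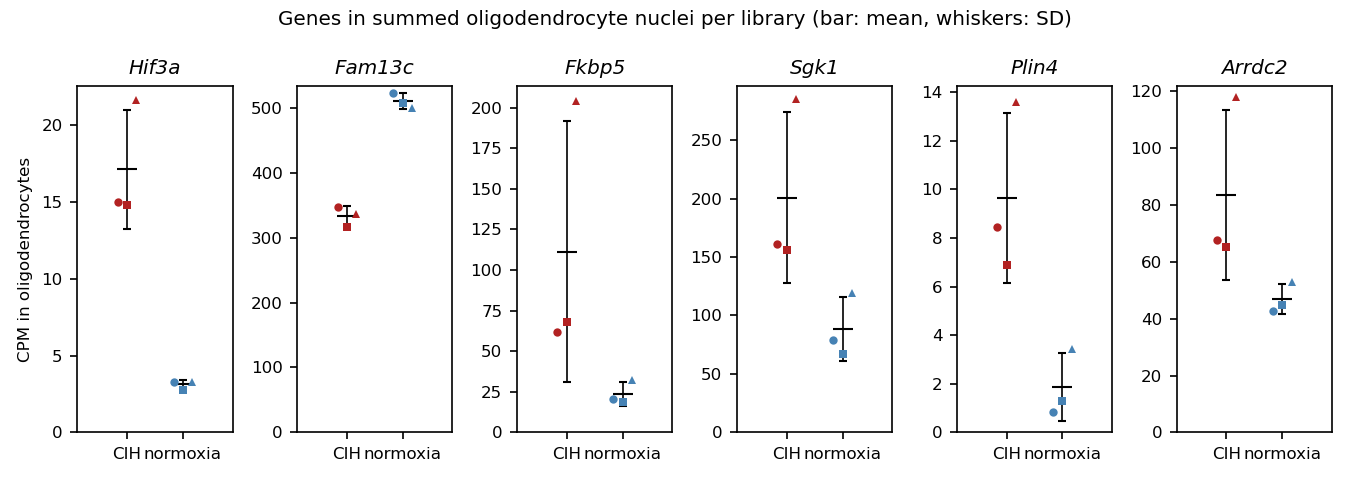
Expression (y axis, CPM) of 6 genes in the summed oligodendrocyte nuclei of each library (points), with group mean (bar) and SD (whiskers). Hif3a sits at 14.8 to 21.6 CPM in CIH and 2.79 to 3.31 in normoxia, Fam13c at 317 to 347 and 500 to 523 CPM, and the third CIH library carries the highest Fkbp5 value.

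In inhibitory neurons the long noncoding RNA Sox2ot rose in CIH, from 173 ± 20.4 to 368 ± 11.4 CPM (log2 fold change 1.08, SE 0.09, adjusted p = 0.000231 in edgeR). It also passed in all neurons together (0.95, SE 0.107, adjusted p = 0.0404). That call ended without the first CIH library (adjusted p = 0.455), the second CIH library (0.306), the first normoxia library (0.331) or the second normoxia library (0.378), and held in 9 of 17 settings (3.55e-11 to 0.455), against 17 of 17 in inhibitory neurons (7.27e-28 to 0.0112). Sox2ot (ENSMUSG00000105265) spans chromosome 3 from 34104270 to 34682619 on the plus strand. It overlaps Sox2 on the same strand and Gm38505 on the other. Sox2ot is among the genes that define inhibitory cluster N4, and this cluster held 33.9% of inhibitory neurons in CIH and 17.9% in normoxia. Cluster N2, whose defining genes include the glycine transporter gene Slc6a5 and Pax2, held 20.7% and 38.4%. Within N4, Sox2ot stood at 1024 ± 123 CPM in CIH and 966.5 ± 308.8 CPM in normoxia. In the third library of each group the N4 share was alike, at 28.0% in CIH and 27.3% in normoxia. Sox2ot in those libraries was 361 and 196 CPM over inhibitory neurons, and 1154.9 and 610.7 CPM within N4. The first and second libraries went the other way within N4, at 1004.4 and 911 CPM in CIH and 1124.2 and 1164.6 CPM in normoxia.

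The inhibitory neuron call was 1 of 13987 genes, with 919 at an unadjusted p under 0.05 (699 expected by chance). DESeq2 called 6, and edgeR called 26 without the third normoxia library and 5 without the third CIH library. All neurons together had 1 call of 16236 genes, 2 in DESeq2, and 8 and 5 without the same libraries. In simulated counts with nothing changed, the same test made 6 calls in all neurons and 0 in inhibitory neurons. In excitatory neurons edgeR and DESeq2 both called 0 of 14342 genes, with 746 at an unadjusted p under 0.05 (717 expected by chance). There edgeR called 16 without the third CIH library and 2 without the third normoxia library. The genes of smallest p there included Chn2 (log2 fold change 0.59, SE 0.118) and Rftn1 (0.53, SE 0.113), both at adjusted p = 0.894. Chn2 is also among the defining genes of granule neurons, which held 1630 to 2230 CPM of it against 39.8 to 71.9 in excitatory neurons. In granule neurons edgeR called 0 of 9716 genes, against 4 in DESeq2, with 392 at an unadjusted p under 0.05 in edgeR (486 expected by chance). Gsg1l, an AMPA receptor auxiliary subunit gene, read 46.7 ± 14.5 CPM in CIH and 5.03 ± 0.48 in normoxia (3.21, SE 0.349, adjusted p = 0.0651). The adhesion molecule gene Ncam2 read 377 ± 37.3 and 132 ± 40.2 CPM (1.53, SE 0.183, adjusted p = 0.0713). In granule neurons edgeR called 4 genes without the third CIH library, Gsg1l among them, and 3 without the third normoxia library.

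**Figure D3:**
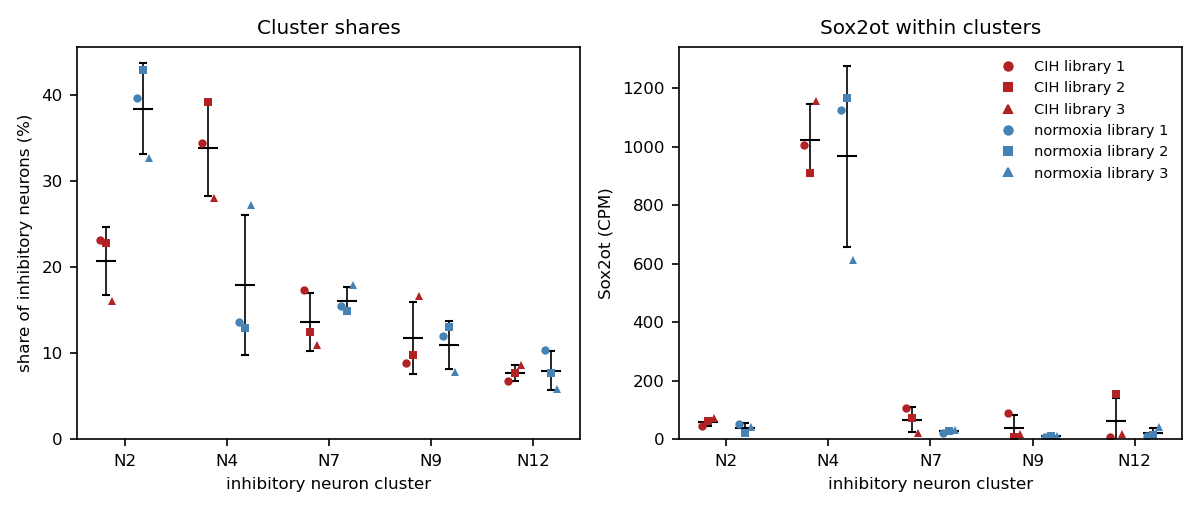
Left, the share of inhibitory neurons (y axis, percent) in each of 5 clusters; right, Sox2ot (y axis, CPM) within the same clusters; points are libraries, bars group means and whiskers SD. The N4 share is 33.9% in CIH and 17.9% in normoxia on average, while Sox2ot within N4 overlaps between the groups.

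In the remaining classes edgeR and DESeq2 called 0 genes each. The numbers at an unadjusted p under 0.05 were 347 of 5197 in astrocytes, 275 of 6191 in microglia, 291 of 3343 in endothelial cells, 136 of 3966 in fibroblasts and 204 of 4184 in oligodendrocyte precursors. Chance alone would give 260, 310, 167, 198 and 209 in the same order. Leaving out the third CIH library gave 16 calls in oligodendrocyte precursors, 3 in astrocytes and 2 in microglia. Astrocytes also had 3 calls without the first CIH library or the third normoxia library, microglia 1 without the third normoxia library and endothelial cells 2 without the second normoxia library. Values nearest the threshold were the metabotropic glutamate receptor gene Grm8 in astrocytes (log2 fold change 1.74, SE 0.334, adjusted p = 0.245) and the scavenger receptor gene Stab1 in microglia (0.95, SE 0.166, adjusted p = 0.285). They also included the carbonic anhydrase gene Car4 in endothelial cells (-1.21, SE 0.243, adjusted p = 0.462), the matrix protein gene Smoc2 in fibroblasts (-1.61, SE 0.382, adjusted p = 0.998) and Cntnap2, a neurexin family gene, in oligodendrocyte precursors (1.17, SE 0.226, adjusted p = 0.388; -0.12 with doublets kept). Counts were simulated from these libraries with known changes. The test recovered 99% of 4-fold and 73% of 2-fold changes among 12743 genes in oligodendrocytes, and 93% and 23% among 3653 genes in fibroblasts. Of the simulated calls, 17 of 189 in oligodendrocytes and 13 of 129 in fibroblasts were false. Both are a larger share than the adjusted p threshold of 0.05 aims for.

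The gene lists fixed before the data were examined gave 262 tests over 30 lists. Camera with its preset correlation called 80, of which 62 were higher in CIH and 18 lower, and 31 were also called in the same direction without the third CIH library. No call held with an estimated correlation (smallest adjusted p = 0.635) or in fry (smallest adjusted p = 0.252). The hypoxia response list in oligodendrocytes had 22 of 32 members higher and a median of 0.17 (0.01 without the third CIH library), and Hif3a was the 1 member that passed, over all genes and when adjusted over the list alone. The list call (adjusted p = 0.0155) had an adjusted p of 0.68 with an estimated correlation. Other members of that list had small values that did not pass, such as Pfkfb3 (-0.34) and Aldoc (0.66, and 0.22 without the third CIH library). Oxidative stress defence genes in granule neurons had 15 of 17 members higher (median 0.25, and 0.06 without that library), 1 of them, the glutathione transferase gene Gstm1 (2.70, SE 0.582), past the threshold when adjusted over the list alone, and adjusted p = 0.68 with an estimated correlation. In oligodendrocyte precursors 8 of 9 glucocorticoid-responsive genes were higher (median 0.78, and 0.30 without that library), 5 of them past the threshold when adjusted over the list alone (adjusted p = 0.68 with an estimated correlation). Zbtb16 read 1.36 there (SE 0.319), and 0.74 without that library. In both classes 3 further lists were higher and turned without the third CIH library. The medians in granule neurons were 0.45 and -0.08 without it for mitochondrially encoded RNAs, 0.25 and -0.25 for ribosomal protein genes and 0.32 and -0.26 for oxidative phosphorylation genes. In oligodendrocyte precursors they were 0.48 and -0.43, 0.38 and -0.37, and 0.52 and -0.16 in the same order. The 6 lists had adjusted p of 0.762, 0.931, 0.915, 0.754, 0.687 and 0.68 with an estimated correlation.

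In all nuclei, circadian clock genes were higher for 19 of 20 members, with a median of 0.36 (0.22 without the third CIH library). Of these, 8 passed when adjusted over the list alone, among them Nr1d1 (0.76), Rora (0.43), Cry1 (0.40) and Npas2 (0.49), and the list had adjusted p = 0.635 with an estimated correlation. Within classes the medians were smaller: 0.20 in oligodendrocytes (-0.00 without the third CIH library), 0.13 in inhibitory neurons (0.14 without it; 15 of 19 members higher, 3 past the threshold when adjusted over the list alone), 0.12 in all neurons (0.06 without it) and 0.07 in granule neurons. The first 3 of these were called at the preset correlation, each with adjusted p = 0.68 with an estimated correlation. Rora is among the defining genes of an unnamed cluster with cerebellar markers. Immediate early genes, which respond to neuronal activity, were higher for 19 of 24 members (median 0.27), with Nr4a3 (0.77, SE 0.163) past the threshold when adjusted over the list alone and adjusted p = 0.68 with an estimated correlation. Angiogenesis and endothelial genes had 20 of 25 members higher (median 0.56, and 0.15 without the third CIH library). Of these, 4 passed when adjusted over the list alone, Ocln (1.50), Pecam1 (1.08), Angpt1 (0.37; -0.20 over named nuclei other than granule neurons without the third CIH library) and Flt1 (1.84, and 0.98 without the third CIH library), and the list had adjusted p = 0.68 with an estimated correlation. Endothelial cells were a larger share of the CIH libraries, as given above. Genes of the choroid plexus and meninges were higher for 12 of 13 members (median 0.93, and 0.59 without the third CIH library), with Dcn (1.10, and 0.69 without it) and Slc6a13 (1.49, and 0.98 without it) past the threshold when adjusted over the list alone and adjusted p = 0.68 with an estimated correlation. Slc6a13 is among the defining genes of a fibroblast cluster, and fibroblasts too were a larger share of the CIH libraries. Reactive astrocyte genes (15 of 21 higher, median 0.25), oligodendrocyte precursor differentiation genes (19 of 21, median 0.43) and p53 targets (17 of 23, median 0.13) were called too, with 2, 1 and 0 members past the threshold when adjusted over the list alone. Without the third CIH library their medians were -0.04, 0.09 and 0.09, and their adjusted p was 0.762, 0.68 and 0.68 with an estimated correlation.

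Hox genes, which mark the caudal levels of the hindbrain, were lower in CIH. In all nuclei 15 of 16 members were lower, with a median of -0.62 (-1.07 without the third CIH library). Of these, 7 passed when adjusted over the list alone, among them Hoxa3 (-0.90, SE 0.145), Hoxb3 (-0.81, SE 0.16), Hoxd3 (-0.94, SE 0.217) and Hoxd4 (-1.06, SE 0.31). The adjusted p was 0.68 with an estimated correlation. The list was also lower in excitatory neurons (11 of 12 members, median -0.46, and -0.83 without the third CIH library) and inhibitory neurons (10 of 11, median -0.37, and -0.80 without it), each with adjusted p = 0.68 with an estimated correlation. In oligodendrocytes 5 of 6 measured members were lower, with a median of -0.23. Granule and Purkinje cell genes of the cerebellum were higher in all neurons named here for 11 of 11 members (median 0.55), with Fat2 (0.99, SE 0.215) past the threshold when adjusted over the list alone and adjusted p = 0.635 with an estimated correlation. They were also higher in excitatory neurons (11 of 11, median 0.45, adjusted p = 0.635 with an estimated correlation) and in oligodendrocytes (9 of 9, median 0.69, adjusted p = 0.68 with an estimated correlation). Midbrain and rostral pons genes were not called with all libraries (inhibitory neurons, 7 members, median 0.23, adjusted p = 0.0647, and adjusted p = 0.68 with an estimated correlation), while Sox14 (1.59) and Gata3 (0.71) passed when adjusted over the list alone. Gata3 is among the defining genes of inhibitory cluster N4, whose mean share of inhibitory neurons was larger in CIH, as given above. Without the third CIH library the list was called by camera with its preset correlation in inhibitory neurons (median 0.88, adjusted p = 0.000181), all neurons (0.69, adjusted p = 8.35e-05) and all nuclei (0.45, adjusted p = 0.0279); with all libraries all 3 had adjusted p = 0.68 with an estimated correlation.

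Lists that track RNA quality differed between the groups, some of them only with the third CIH library. Ribosomal protein genes were higher for 63 of 63 members in all nuclei (median 0.50, and 0.02 without the third CIH library) and lower for 61 of 62 in endothelial cells (median -0.63, and -0.43 without it), with adjusted p of 0.694 and 0.68 with an estimated correlation. Mitochondrially encoded RNAs were higher for 9 of 9 members in astrocytes (median 0.66, and 0.54 without that library), 7 of them past the threshold when adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes were higher for 36 of 42 (median 0.32, and 0.08 without it), 6 of them past it; both had adjusted p = 0.68 with an estimated correlation. Astrocytes also carried higher myelin genes (14 of 16, median 0.39, and 0.00 without that library; 2 passed when adjusted over the list alone, Cnp at 1.14 (0.61 without it) and Mobp at 1.08) and synaptic vesicle genes (13 of 17, median 0.35; 1 passed when adjusted over the list alone, Snap25 at 0.92), with adjusted p = 0.68 with an estimated correlation for both lists. Blood genes in oligodendrocytes were higher for 7 of 7 members (median 0.50, and 0.08 without that library), 0 of them past the threshold when adjusted over the list alone (adjusted p = 0.687 with an estimated correlation).

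The other called lists had 0 members past the threshold when adjusted over the list alone in the class of their smallest p. Microglial activation genes in microglia were lower for 11 of 14 members (median -0.17; the lysosomal gene Cd68 -0.67, SE 0.256), and interferon response genes in endothelial cells for 11 of 12 (median -0.37; Gbp3 -1.25, SE 0.443). Lower values also held for cholesterol biosynthesis genes in astrocytes for 15 of 17 (median -0.28) and unfolded protein response genes in granule neurons for 14 of 16 (median -0.11; Hsp90b1 -0.37, SE 0.144). Heat shock genes (15 of 17, median 0.10; Stip1 0.36, SE 0.109) and glutamate receptor genes (20 of 23, median 0.09; Grik1 0.32, SE 0.108, and 0.17 without the first CIH library) were higher in inhibitory neurons. All 6 had adjusted p = 0.68 with an estimated correlation. Without the third CIH library the medians were -0.14 for interferon response, -0.10 for cholesterol biosynthesis, -0.18 for unfolded protein response, 0.07 for heat shock and 0.05 for glutamate receptor genes. In inhibitory neurons mitochondrially encoded RNAs (9 of 11 higher, median 0.27, and 0.03 without that library) and ribosomal protein genes (45 of 63, 0.05, and -0.04) were called too, with adjusted p of 0.68 and 0.816 with an estimated correlation. Besides midbrain and rostral pons genes, 5 lists had no call in any class. Their smallest adjusted p was 0.0687 for GABA and glycine signalling (microglia, median -0.33), 0.382 for monoamine synthesis (all neurons, 0.03), 0.0941 for respiratory control peptides and receptors (all nuclei, -0.19), 0.101 for potassium channels (excitatory neurons, 0.04) and 0.217 for extracellular matrix (astrocytes, -0.04). Of the respiratory control genes in all nuclei, the serotonin receptor genes Htr7 (-0.46, SE 0.104) and Htr2c (-0.49, SE 0.129) and the opioid peptide gene Penk (-0.43, SE 0.132) did not pass when adjusted over the list alone.

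The effect of CIH was compared between pairs of classes in the same libraries. Excitatory and inhibitory neurons differed for 6 of 13751 genes (limma, adjusted p under the threshold), all with a higher value in inhibitory neurons. The transcription factor gene Maf had a log2 fold change of -0.51 in excitatory and 0.86 in inhibitory neurons (adjusted p of the difference 0.00195), Sox2ot -0.16 and 1.08 (0.036), and the potassium channel gene Kcnh8 -0.30 and 0.37 (0.036). Etl4, Tmem108 and 6330411D24Rik made up the remainder. Maf and Kcnh8 are among the defining genes of excitatory cluster N11. This cluster held 4.4, 5.7 and 10.8% of excitatory neurons in the CIH libraries and 10.9, 10.9 and 9.4% in the normoxia libraries. Genes named in this paragraph other than Sox2ot and Fam13c were chosen after their values were seen. All neurons and oligodendrocytes differed for Fam13c, at 0.11 and -0.61 (adjusted p = 0.0253), and for Gm38505, at 0.60 and -0.85 (adjusted p = 0.0283), of 12589 genes tested. Gm38505 is among the defining genes of inhibitory cluster N4, whose share of inhibitory neurons differed between the groups, as given above. Astrocytes and oligodendrocytes differed for 1 of 4996 genes, Gli2, a transcription factor of the Hedgehog pathway, at 0.09 and 4.25 (adjusted p = 0.0184). Despite the size of the oligodendrocyte value, edgeR called Gli2 in neither class. Leaving out 1 library moved these counts from 6 to between 0 and 35, from 2 to between 0 and 33 and from 1 to between 0 and 2. The highest counts of the first and second pair came without the third CIH library, and that of the last pair without the first CIH library.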

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

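All tests of explanations in this part were chosen after the result to be explained was seen. For those of astrocyte and endothelial RNA only the predictions were written beforehand. The splits of the libraries and the class differences were planned.

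The effect of CIH differed between cell classes by a test of the difference itself: 6 genes between excitatory and inhibitory neurons, 2 between all neurons and oligodendrocytes, and 1 between astrocytes and oligodendrocytes. The classes are not the same mix of clusters in each group: cluster N4, which Sox2ot and Gm38505 help define, held 17.9% of inhibitory neurons in normoxia and 33.9% in CIH. Excitatory cluster N11, which Maf and Kcnh8 help define, held 10.4% of excitatory neurons in normoxia and 7.0% in CIH (10.8% in the third CIH library). The Sox2ot difference between classes thus need not be a change within cells. The same holds for Maf and Kcnh8 on the excitatory side and Gm38505 on the neuronal side. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and for each of these counts 1 of the 10 splits gave as many, the real one, with 0 as the highest of the others. Leaving out 1 library moved the counts to between 0 and 35, 0 and 33, and 0 and 2, as given above with the libraries.

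Glucocorticoid-responsive genes stood higher in CIH oligodendrocytes, with a median log2 fold change of 0.81; without the third CIH library, which as the only cause would leave a median near 0, it was 0.293, 15 of 17 members were higher and 11 lay above all normoxia libraries in both other CIH libraries. RNA of astrocytes in these nuclei, at the largest share the markers allow (1.29%), would give a median of 4.44% of the members' rise, and RNA of endothelial cells (0.284%) 1.76%. Both values rest on the profiles of nuclei named as these classes, so foreign RNA of any other origin was not tested. A shift between oligodendrocyte clusters would leave no rise within clusters, and the lowest of 4 within-cluster medians was 0.554. Stress of the exposure, handling and the hour at which tissue was taken all may raise such genes and stay open, as untested; 2 of 10 splits gave as many members past the threshold when adjusted over the list alone (11 in the real one), the highest other being 12, with 10 splits too few for a share under 0.05. The split with 12 put the third libraries of both groups on one side with the first CIH library, and the list's adjusted p was 0.68 with an estimated correlation.

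Sox2ot was higher in CIH inhibitory neurons, and Hox genes were lower in CIH neurons. More nuclei of the Sox2ot-expressing cluster N4 in the CIH libraries is a candidate explanation for the first: over the 5 of 8 inhibitory clusters with at least 20 nuclei in every library, the log2 ratio was 0.221 with clusters weighted alike and 1.17 in their sum (Sox2ot helps define N4, so part of this fall follows from the clustering). The N4 share does not separate the third libraries (28.0% in CIH, 27.3% in normoxia), where Sox2ot within N4 was 1154.9 and 610.7 CPM. The first and second libraries went the other way within N4, at 1004.4 and 911 CPM in CIH and 1124.2 and 1164.6 CPM in normoxia. The groups thus overlapped within N4. The same weighting left the Hox genes at a median of -0.381, against -0.451 in the sum of these 5 clusters, with 11 of 11 members lower. In excitatory neurons, over 4 of 10 clusters, it left -0.483 against -0.566, with 10 of 11 lower, so a different mix of these clusters was not the whole cause within them. A piece of tissue that reached further rostrally in the CIH libraries could give both. Midbrain and rostral pons genes were not called in inhibitory neurons with all libraries (camera, adjusted p = 0.0647, and 0.68 with an estimated correlation). They were called there without the third CIH library (adjusted p = 0.000181 at the preset correlation). Gata3 of that list also helps define N4. Such a reach of the tissue was not tested apart from the exposure, and a loss of particular neurons under CIH stays open too. In oligodendrocytes 5 of 6 measured Hox genes were also lower (median -0.228). Neuronal RNA in the oligodendrocyte sums was not tested, so these values do not decide on a loss of neurons.

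Without the third CIH library 487 genes passed in all nuclei, against 0 with it. Granule neurons and unnamed nuclei in the sums are a candidate explanation: without these nuclei, and without that library, 15 genes passed, 13 of them among the 487. The CIH libraries left in that fit were close to each other (chi-square per gene 2.52), and the small spread this gives stays open as a further source of calls. The first and second CIH libraries held 24.75 and 27.43% granule neurons, and the cerebellum lies next to the pons and medulla, so the dissection may have differed; a real change in granule neurons was not tested apart from it.

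For the counts of changed genes per class, 10 splits are too few for a share under 0.05. As many calls as the real split came from 1 of 10 splits in all neurons (1 call, highest other 0) and in oligodendrocytes (2 calls, highest other 0), and from 2 of 10 in inhibitory neurons (1 call, highest other 1). In the classes with 0 calls all 10 splits gave as many; the highest other was 19 in astrocytes, 1 in oligodendrocyte precursors and 0 in all nuclei, granule neurons, endothelial cells, excitatory neurons, fibroblasts and microglia. For the gene lists 5 of 10 splits gave as many calls as the real 80, and the highest other was 103. The 19 astrocyte calls came from the first CIH library with the first and second normoxia libraries against the rest; a count that far above the real 0 leaves open a structure of the samples other than the exposure, which was not tested.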

How the results depend on the processing

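The automatic doublet threshold and the sums or shares over named nuclei other than granule neurons were chosen after the data were seen; the other alternatives were planned. Of the named genes' values under the alternatives, 2412 kept direction and side of the threshold, 148 came to pass it, 21 no longer passed and 5 reversed; the cause was not tested for any of the changes in this part. Simulated 2-fold changes were recovered for 23% of genes in fibroblasts and 37% in endothelial cells, the classes whose shallowest library held the fewest UMIs and also with the widest spread between libraries (23.3 and 21.6%), so depth and spread were not separated.

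In all nuclei the 0 calls of edgeR became 178 in DESeq2, 4 with no low-count filter, 2 with doublets kept, 2 with the automatic threshold, 7 over named nuclei other than granule neurons and 15 over these without the third CIH library. With no low-count filter calls were 18 in all neurons, 37 in astrocytes, 77 in granule neurons, 19 in endothelial cells, 82 in excitatory neurons, 26 in fibroblasts, 91 in inhibitory neurons, 6 in microglia, 140 in oligodendrocytes and 24 in oligodendrocyte precursors. DESeq2 gave 2 in all neurons, 4 in granule neurons, 6 in inhibitory neurons and 30 in oligodendrocytes. With median UMIs as a covariate calls were 2 in astrocytes, 3 in granule neurons, 2 in endothelial cells, 3 in inhibitory neurons, 3 in microglia, 9 in oligodendrocytes and 14 in oligodendrocyte precursors. Nuclei with at least 1000 genes and at most 1% mitochondrial UMIs gave 2 in granule neurons and 1 in oligodendrocyte precursors. Oligodendrocytes had 1 call with RLE size factors, doublets kept, resolution 2 or the automatic threshold and 0 adjusted over all classes together; inhibitory neurons had 2 at resolution 2 and 2 with the automatic threshold; all neurons had 0 with doublets kept, with the automatic threshold and adjusted over all classes together.

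With a replicate block calls were 0 in all neurons, 6 in astrocytes, 21 in granule neurons, 21 in endothelial cells, 1 in excitatory neurons, 9 in inhibitory neurons, 6 in microglia and 120 in oligodendrocytes, and 22 genes differed between all neurons and oligodendrocytes. Same-numbered libraries deviated together with r of 0.03, 0.19 and 0.2 in all nuclei, so the numbers were not taken to pair the samples. CIH library 1 correlated best with another number there (0.17). In oligodendrocytes every such r was over 0.1 (0.14, 0.21 and 0.41). Libraries 1 and 2 of unlike number gave 0.14 and 0.18 too, so pairing by number was left open there. A wider division ran across both groups in all nuclei, all neurons, oligodendrocytes and microglia. Libraries 1 and 2 deviated together (0.03 to 0.21), and so did those numbered 3 (0.2, 0.2, 0.41 and 0.32). Number 3 against 1 or 2 was negative throughout (-0.04 to -0.3). In all nuclei those numbered 3 were still far apart (chi-square per gene 62.1). The block also takes up this division, the 10 splits do not hold it fixed, and the source of the division was not tested.

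Leaving out 1 library at a time gave 0 to 487 calls in all nuclei, 0 to 8 in all neurons, 0 to 3 in astrocytes, 0 to 4 in granule neurons, 0 to 2 in endothelial cells, 0 to 16 in excitatory neurons, 1 to 26 in inhibitory neurons, 0 to 2 in microglia, 0 to 12 in oligodendrocytes and 0 to 16 in oligodendrocyte precursors. The class differences ranged from 0 to 35 between excitatory and inhibitory neurons, 0 to 33 between all neurons and oligodendrocytes and 0 to 2 between astrocytes and oligodendrocytes. The highest values came without the third CIH library, except in all neurons and inhibitory neurons (without the third normoxia library), endothelial cells (without the second normoxia library), astrocytes (without the first CIH, the third CIH or the third normoxia library) and the last pair (without the first CIH library).

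Among shares, the perivascular macrophage difference of -0.05 percentage points became 0.06 in nuclei with at least 1000 genes, 0 with doublets kept and 0.08 over named nuclei other than granule neurons, the oligodendrocyte difference of -6.16 became 0.58 over those, and the oligodendrocyte precursor difference of 0.72 ranged from -0.06 (without the third CIH library) to 1.17. The 80 list calls became 0 with an estimated correlation and 0 in fry, and 60 to 97 with 1 library left out. The monoamine list median of 0.03 ranged from -0.041 to 0.226 and the potassium channel median of 0.04 from 0.013 to 0.087. Peg3 in fibroblasts (1.27) read -0.017 with doublets kept, Cntnap2 in oligodendrocyte precursors (1.17) -0.522 in nuclei with at least 1000 genes and -0.116 with doublets kept, Angpt1 in all nuclei (0.37) -0.198 over named nuclei other than granule neurons without the third CIH library, and Gabrb1 in microglia (0.57) -0.314 to 0.921 with 1 library left out.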

Other observations

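All tests in this part were chosen after the result was seen.

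Gm47283, a predicted gene on chromosome Y (90784738 to 90816464), was chosen after its values were seen. It was higher in all 3 CIH libraries than in all 3 normoxia libraries in each of 9 classes and in all neurons together. Chance gives this in this direction for 5% of genes in 1 class. Its log2 fold changes ran from 0.90 to 1.43. It passed the threshold in none of these sums, which come from the same libraries. In astrocytes the normoxia libraries read 45.7, 36.2 and 124 CPM and the CIH libraries 150, 170 and 197. A difference between the animals other than the exposure was not tested. Of the clock genes in all nuclei, Arntl, Npas2 and Clock, which run opposite to the Per, Dbp and Nr1d1 group over the day, had a median of 0.073 with values in both directions (0.07, 0.49 and -0.05), and the other 8 genes had a median of 0.406, so tissue taken at another clock time cannot be told apart from an effect of CIH.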
